A study of Mus musculus with 12 samples.

How the data were processed

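Ribosome footprints and mRNA were measured in Neuro2a cells, a mouse neuroblastoma line with neuronal features, after transfection of siRNA against Ebp1 or of a control siRNA. Ebp1 is the protein made from the Pa2g4 gene. Per the labels' protocols, cultures were grown in biological triplicate, the siEbp1 oligonucleotides were a commercial pool, and the control was a non-targeting siRNA that the titles call scrambled. Lysis buffer contained cycloheximide. Footprints were generated with RNase I, ligated to adapters, gel-purified and amplified by PCR. The RNA libraries were enriched for poly(A) from the lysate and prepared with a directional kit, per the labels. The series design states that each culture gave both a footprint and an RNA library. This made 4 groups of 3 libraries, 12 in all.

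The deposited values were raw read counts per gene for the 12 libraries in one table, whole numbers that had not been normalised. Reads had been aligned with STAR 2.7.0 to the mouse build GRCm38, per the submitters' processing notes. The counting program, the annotation release, the part of the gene counted, the strand setting, the removal of ribosomal RNA reads, the handling of PCR duplicates and the treatment of reads with several matches are not given in the sources used here. Footprints are short, so genes with near-identical copies, such as ribosomal protein and histone genes, can lose or exchange counts between copies, and their values are uncertain. Without the strand setting, the same holds for overlapping and antisense genes. PCR duplicates may be counted as separate molecules, so the counting floors cover counting error only. A floor of 3 counts in a library corresponded to between 0.146 and 0.635 CPM (counts scaled to a fixed library total) in footprints and between 0.356 and 0.453 CPM in RNA.

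The table held 22544 genes. Its versioned gene identifiers were matched without the version to GENCODE M21, which is on GRCm38, and 22444 had a match, of which 21679 were protein coding. The other 100 had no match and so no gene name here. Every column of counts had a sample. Coordinates are from that annotation, 1-based. Total counts were between 4720773 and 20548094 in the footprint libraries and between 6624627 and 8421932 in the RNA libraries. No 2 libraries of one group agreed within counting noise: the chi-square per degree of freedom was between 3.02 and 22.3 in all pairs.

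The choices of tests, gene lists, naming rule and alternative settings were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr low-count filter, robust quasi-likelihood fits and F tests. RNA was compared in the 6 RNA libraries and footprints in the 6 footprint libraries. Translational efficiency, the ratio of footprints to mRNA, was tested as the interaction of assay and treatment in one model over all 12 libraries, on genes that passed the filter in both assays. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and SE is the log2 fold change divided by the square root of F. CPM values in the text were scaled by TMM within each assay, except where they are said to be per library total. Per-culture ratios were differences of log2 CPM with a prior count of 2. The labels call the replicates biological, and p-values measure the spread between these cultures.

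Named genes were chosen by a rule. It took Pa2g4 and, per comparison, the 10 largest increases and the 10 largest decreases among genes with an adjusted p under the threshold, a mean of at least 4 CPM and 3 Ebp1 siRNA values all on one side of the 3 control values. Where under 5 genes passed in a direction, the 5 with the smallest p were named and said not to pass. The rule named no predicted genes or pseudogenes, and 1 gene that it named is not reported here. For each gene list described, up to 4 members with the smallest p were named. A list was described where its adjusted p was under 0.05 or at least 25% of its measured members were called.

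In all, 33 gene lists were fixed, covering the translation machinery, stress responses, the cell cycle, metabolism, neuronal functions, and markers of the neuroblast lineage and of other cell types. Of these, 31 had at least 3 measured members. They were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Lists of translational efficiency were tested on the per-culture ratios.

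Alternatives were DESeq2 1.42.0, RLE and upper-quartile size factors, no filter, a filter of 4 CPM, removal of mitochondrial, histone and predicted genes, a log2 fold change of at least 0.5, the replicate number as a block, a culture block, 1 fit over all 12 libraries, TMM within each assay, limma on the per-culture ratios, and leaving out each replicate. After seeing the data, DESeq2 fold changes and leaving out each library were added for the correlation across genes, and 3 further kinds: removal of each library's smooth trend with coding GC content and coding length (natural splines with 4 degrees of freedom each), thinning of the footprint libraries to the smallest RNA total, and removal of genes with a site of either of 2 heptamers in the 3' UTR. The heptamer sites were searched in the annotated 3' UTRs of at least 30 bases.

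The replicate numbers did not pair the control and Ebp1 siRNA libraries in RNA, as the closing section reports. In footprints, libraries of the same number deviated weakly in the same direction. The pairing of a footprint with an RNA library rests on the series design, which ties both to one culture. The deviations of the 2 libraries of a culture from their group means correlated between -0.01 and 0.20 across genes.

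The fits were tested on simulated counts drawn gene by gene. Each gene had 1 mean over the libraries of an assay, scaled by library totals, and all genes of an assay shared 1 dispersion. The simulation held no gene-specific spread and no trends within a library, so it may overstate recovery and understate false calls in these data. Of 67 genes changed by 1.5-fold, 38.8% were recovered in the RNA comparison of 11302 genes, 76.1% in the footprint comparison of 11256 genes and 23.9% in the translational efficiency comparison of 10894 genes. At a fold of 2 the shares were 92.5%, 97.0% and 82.1%. At a fold of 4, with 66 genes, they were 100%, 100% and 95.5%. In each of the 3 simulations 5 genes were called falsely.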

Results

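Ebp1, encoded by Pa2g4, is a protein that binds ribosomes and has been linked to growth control. The study asked how its depletion changes mRNA levels and ribosome occupancy in Neuro2a cells. The data comprised 12 libraries: ribosome footprints and poly(A)-enriched RNA from 3 cultures with control siRNA and 3 cultures with Ebp1 siRNA. Footprint libraries of replicates 1, 2 and 3 held 20548094, 14070091 and 17839631 counts with control siRNA and 4720773, 15488399 and 14273234 counts with Ebp1 siRNA. RNA libraries held 8421932, 6624627 and 7248403 counts with control siRNA and 7597561, 6680466 and 7685117 counts with Ebp1 siRNA.

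The targeted gene was examined first. Pa2g4 (ENSMUSG00000025364.12; GRCm38 chromosome 10, 128557766 to 128565987, minus strand, 12 exons in the transcript with the longest coding sequence) was low in all 6 Ebp1 siRNA libraries. Its RNA level, per library total, was 960, 972 and 811 CPM in the controls (8083, 6442 and 5879 counts) and 47.4, 30.1 and 37.0 CPM after Ebp1 siRNA (360, 201 and 284 counts). Its footprints were at 827, 801 and 738 CPM in the controls (16984, 11277 and 13168 counts) and 52.3, 29.7 and 33.3 CPM after Ebp1 siRNA (247, 460 and 476 counts). The log2 fold change was -4.59 (SE 0.18, adjusted p = 1.62e-05) in RNA, a 24.1-fold reduction, and -4.46 (SE 0.21, adjusted p = 3.77e-06) in footprints. Footprints per mRNA of Pa2g4 did not pass the test (log2 fold change 0.15, SE 0.26, adjusted p = 0.965).

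**Figure D1:**
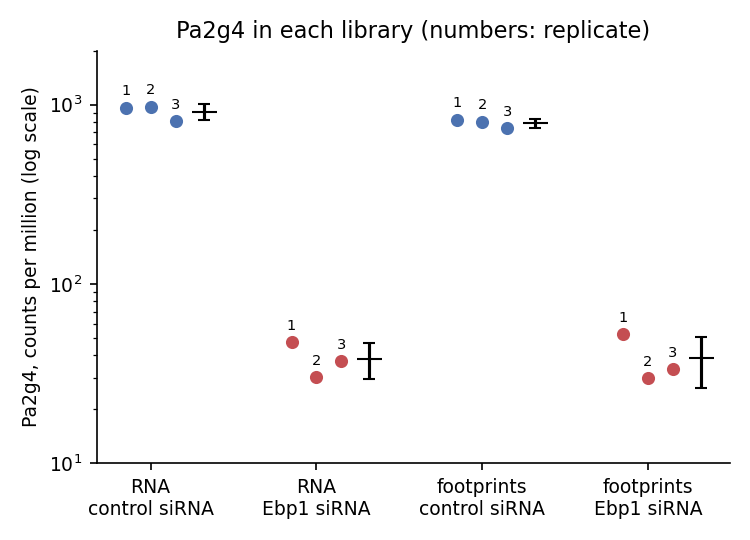
Pa2g4 CPM, scaled by each library total, (log axis) in the 12 libraries, 3 per group; points are libraries with their replicate numbers, and the bar beside them is the mean with SD. The 6 control libraries lay between 738 and 972 CPM and the 6 Ebp1 siRNA libraries between 29.7 and 52.3 CPM.

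At the RNA level, few genes besides Pa2g4 were called, and most of those fell. Dbh (ENSMUSG00000000889.8; chromosome 2, 27165233 to 27183200), whose enzyme converts dopamine to noradrenaline, fell from 14.1 ± 2.18 to 2.26 ± 0.295 CPM (SD, n = 3). This was a log2 fold change of -2.63 (SE 0.21, adjusted p = 0.00205). Ddc (ENSMUSG00000020182.16; chromosome 11, 11814101 to 11898144), whose enzyme makes dopamine from L-DOPA, rose from 14.2 ± 1.94 to 38.5 ± 3.36 CPM. Its change was a log2 fold change of 1.44 (SE 0.15, adjusted p = 0.00808). Of 11302 genes tested with edgeR's quasi-likelihood F test, 84 changed at an adjusted p under 0.05, 13 higher and 71 lower. Among them 6 of the higher and 24 of the lower genes changed by at least 2-fold. The median absolute log2 fold change of the 84 genes was 0.90. An unadjusted p under 0.05 was reached by 1638 genes, where 565 were to be met by chance. The 3 Ebp1 siRNA values lay wholly above or below the 3 control values in 21.5% of genes, where chance gives 10%. Genes are not independent, so library structure can also give such an excess. A split of control replicates 1 and 2 and Ebp1 siRNA replicate 3 against the other libraries gave 2891 genes with such a p. The remaining splits that mixed the treatments gave between 59 and 780. Neither the excess nor the number called thus measures how many mRNAs responded to Ebp1 siRNA.

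The other large increases were in Ppp1r3f, a regulatory subunit of protein phosphatase 1 (log2 fold change 1.54, SE 0.24), the collagen chains Col11a2 (1.43, SE 0.21) and Col22a1 (0.91, SE 0.14), and Gsdmd, the pore-forming protein of pyroptosis (1.25, SE 0.21). Spef1 (1.24, SE 0.17), Lmbr1l (0.90, SE 0.13), the homeobox gene Hlx (0.71, SE 0.12) and the lysophospholipase gene Pnpla7 (0.64, SE 0.11) also rose. Their adjusted p-values were between 0.0243 and 0.0464.

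Besides Pa2g4 and Dbh, the largest decreases were in Lrrn4 (log2 fold change -1.70, SE 0.27), Pdlim3, which encodes a PDZ and LIM domain protein of actin filaments (-1.58, SE 0.18), the BAR domain gene Bin3 (-1.54, SE 0.15) and the ubiquitin ligase gene Rnf166 (-1.51, SE 0.16). Fmnl1, a formin that acts on actin (-1.45, SE 0.12), Isca2, a mitochondrial iron-sulfur cluster assembly factor (-1.41, SE 0.15), Lix1 (-1.34, SE 0.20), Npdc1 (-1.31, SE 0.18) and the intermediate filament gene Sync (-1.29, SE 0.20) fell as well. Their adjusted p-values were between 0.00205 and 0.0327. Of the 10 genes named as largest decreases, Bin3, Rnf166, Isca2, Lix1, Npdc1 and Sync held in their annotated 3' UTRs a copy of the heptamer CTCACCT or GAACCCT, both of which occur in the Pa2g4 coding sequence. So did Spef1 and Col22a1 among the named increases, and 19.1% of all 10950 genes searched.

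None of the 31 gene lists passed camera at the RNA level, with the smallest adjusted p at 0.0534. With the GC and length trend removed, mesenchymal markers (median -0.49, adjusted p = 0.0241) and neurite and neuronal cytoskeleton genes (median -0.15, adjusted p = 0.0254) passed, each with an adjusted p = 0.607 with an estimated correlation. Without that correction, the smallest value was reached by targets of ATF4, the transcription factor of the integrated stress response (median log2 fold change 0.11, 23 of 33 members positive), and by mesenchymal markers (median -0.50, 9 of 11 members negative). None of the ATF4 targets and none of the mesenchymal markers was called among all genes. Adjusted over the list alone, 1 ATF4 target was higher and 4 mesenchymal markers were lower. The number of RNA genes called rested on single libraries. It was 793 (300 higher and 493 lower) without Ebp1 siRNA replicate 3, and 20, 11, 11, 8 and 4 without Ebp1 siRNA replicate 2, Ebp1 siRNA replicate 1, control replicate 1, control replicate 3 and control replicate 2. It was 292 with DESeq2, 146 without a low-count filter, 419 (134 higher and 285 lower) in 1 fit over all 12 libraries, 364 (92 higher and 272 lower) with each library's trend with coding GC content and length removed and 36 among genes without a site of either heptamer.

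Ribosome footprints were called changed in many more genes, about as often up as down and mostly by less than 2-fold. The signal recognition particle gene Srp72 (ENSMUSG00000036323.14; chromosome 5, 76974683 to 76999937) fell from 243 ± 14.4 to 91.8 CPM, a log2 fold change of -1.41 (SE 0.09, adjusted p = 1.64e-08), while its RNA changed by -0.99 (SE 0.11, adjusted p = 0.0087). The lipid transporter gene Abca1 (ENSMUSG00000015243.4; chromosome 4, 53030787 to 53159895) rose from 29.96 ± 4.06 to 66.1 ± 6.90 CPM of footprints, a log2 fold change of 1.15 (SE 0.11, adjusted p = 1.62e-06). Of 11256 genes tested, 2667 changed at an adjusted p under 0.05, 1269 higher and 1398 lower. The balance was 1461 higher and 1128 lower with upper-quartile size factors, and 950 and 840 in 1 fit over all libraries. TMM scales the libraries to a common centre, and the median log2 fold change of all genes was 0.01. The balance thus depends on the scaling, and a change common to all genes would not be seen. At least 2-fold changes were seen in 126 of the higher and 79 of the lower genes, and the median absolute log2 fold change of called genes was 0.47. The 3 Ebp1 siRNA values lay wholly above or below the 3 control values in 4380 genes, 38.9% of those tested, where chance gives 10%.

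Other large increases in footprints were in Gsdmd (log2 fold change 1.65, SE 0.20), Lmbr1l (1.60, SE 0.20), Rnf165 (1.32, SE 0.22), the triglyceride synthesis gene Dgat2 (1.29, SE 0.17) and Relt, a receptor of the tumor necrosis factor receptor family (1.24, SE 0.18). The receptor gene Calcrl (1.21, SE 0.16), the proteasome subunit gene Psmb5 (1.20, SE 0.27) and Pgap3, which acts on GPI anchors (1.16, SE 0.21), followed. Adjusted p-values of these genes were between 1.86e-05 and 0.0136. In RNA, Gsdmd and Lmbr1l passed the test. The RNA values of the others were all positive but did not pass, from 0.25 (SE 0.13) for Psmb5 to 1.26 (SE 0.41) for Calcrl.

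The largest decreases in footprints besides Pa2g4 were in Dbh (log2 fold change -2.65, SE 0.21), Bin3 (-1.98, SE 0.19), the O-glycan synthesis gene C1galt1 (-1.56, SE 0.18), Lix1 (-1.56, SE 0.15), Isca2 (-1.53, SE 0.14) and Pdlim3 (-1.48, SE 0.23). They were followed by the calcium-binding protein gene S100a4 (-1.41, SE 0.18), Patl1, a factor of mRNA decapping (-1.41, SE 0.12), Srp72, and Tph1, whose enzyme starts serotonin synthesis (-1.40, SE 0.15). Adjusted p-values of these genes were between 1.64e-08 and 0.00104. All 10 were lower in RNA too, and S100a4 and Patl1 did not pass the test there (adjusted p = 0.0623 and 0.0746). Bin3, C1galt1, Lix1, Isca2, Patl1 and Srp72 held a 3' UTR copy of CTCACCT or GAACCCT, as did Relt among the named increases.

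Translation machinery genes moved in both directions in the footprints. Translation initiation and elongation factors were lower as a list (camera adjusted p = 0.00715; adjusted p = 0.802 with an estimated correlation). Of its 45 members 14 fell, 2 rose and 29 did not pass. Adjusted over the list alone 15 fell and 2 rose. Eif5b, the subunit-joining factor, fell by 0.66 on the log2 scale (SE 0.10), and Eif3a by 0.56 (SE 0.09), Eif3c by 0.44 (SE 0.09) and Eif2b3 by 0.44 (SE 0.09). Genes of 60S subunit biogenesis and export were lower (adjusted p = 0.0331; adjusted p = 0.802 with an estimated correlation). Of its 39 members 11 were called lower and none higher, and 13 were lower and 0 higher adjusted over the list alone. Among them were the AAA ATPase gene Nvl (-0.90, SE 0.10), the nucleolar protein genes Ncl (-0.68, SE 0.11) and Npm1 (-0.57, SE 0.12), and Rpf1 (-0.49, SE 0.09). Genes of 40S subunit biogenesis were lower too (adjusted p = 0.0331; adjusted p = 0.802 with an estimated correlation). Of 34 genes 12 fell, such as Ltv1 (-0.46, SE 0.11), Pno1 (-0.41, SE 0.10) and Mphosph10 (-0.40, SE 0.11). Another 2 rose, Nol6 among them (0.43, SE 0.10), and the counts adjusted over the list alone were the same. Nvl, Eif3a, Eif3c and Pno1 held a 3' UTR copy of a heptamer.

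Large ribosomal subunit proteins were higher as a list (median log2 fold change 0.51, camera adjusted p = 0.0391; adjusted p = 0.802 with an estimated correlation). Of 40 measured members, 12 rose, 8 fell and 20 did not pass, with 15 higher and 8 lower adjusted over the list alone. Among the rises were Rpl38 (2.15, SE 0.37; 0.39 to 1.76 CPM), Rpl12 (1.24, SE 0.21; 2.31 to 5.52 CPM) and Rpl41 (0.99, SE 0.16; 12.4 to 24.7 CPM). The more abundant Rpl4 fell by 0.47 on the log2 scale (SE 0.09). In the small ribosomal subunit list 5 of 26 members rose, such as Rps12 (0.78, SE 0.19) and Rps2 (0.55, SE 0.10). Another 3 fell, such as Rps4x (-0.85, SE 0.13) and Rps15a (-0.50, SE 0.13). The list did not pass (adjusted p = 0.227). Adjusted over the list alone 6 rose and 4 fell. Ribosomal protein genes together took between 0.612% and 0.834% of footprint counts and between 2.34% and 3.30% of RNA counts. Of 77 mitochondrial ribosomal proteins 12 rose, such as Mrpl20 (0.48, SE 0.10) and Mrps7 (0.43, SE 0.10). Another 11 fell, such as Mrpl28 (-0.46, SE 0.10) and Mrps15 (-0.43, SE 0.10). The counts were 14 and 13 adjusted over the list alone, and the list did not pass (adjusted p = 0.740).

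The 7 measured mitochondrially encoded mRNAs were higher as a list in footprints (median log2 fold change 0.81, 7 of 7 positive, camera adjusted p = 0.00212; adjusted p = 0.802 with an estimated correlation). None was called, either among all genes or adjusted over the list alone. The estimated inter-gene correlation of the list was 0.98, so the 7 values are not separate observations. mt-Nd5 stood at 1.03 (SE 0.37), mt-Cytb at 0.93 (SE 0.38), mt-Nd4 at 0.81 (SE 0.30) and mt-Nd2 at 0.80 (SE 0.31). Their share of footprint counts was 1.13%, 0.981% and 1.60% in the controls and 3.28%, 2.11% and 1.56% after Ebp1 siRNA, so the groups overlapped. In RNA the share was between 2.52% and 2.88% in all 6 libraries, and 6 of the 7 values were negative, but with the GC and length trend removed their RNA median was 0.25 (list adjusted p = 0.0642).

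Replication-dependent histones were higher as a list in footprints (median log2 fold change 0.17, adjusted p = 0.0163; adjusted p = 0.802 with an estimated correlation). Of 55 members 13 rose, such as Hist1h3g (0.87, SE 0.14), Hist1h1d (0.52, SE 0.10) and Hist4h4 (0.50, SE 0.10). Another 2 fell, such as Hist1h2ag (-0.65, SE 0.11), with 15 higher and 2 lower adjusted over the list alone. With the trend with coding GC content and length removed, the median of this list was -0.22 and its direction turned. The camera adjusted p was then 0.0469, or 0.941 with an estimated correlation, and of 54 members 3 rose and 9 fell. Histone genes took between 1.10% and 1.37% of footprint counts and at most 0.00361% of the counts of the poly(A)-enriched RNA. Targets of ATF4 and the integrated stress response were higher (median 0.15, adjusted p = 0.00715; adjusted p = 0.802 with an estimated correlation). Of 33 genes 6 rose and 1 fell, with 8 higher and 1 lower adjusted over the list alone. The stress genes Ddit3 (0.89, SE 0.16), Sesn2 (0.75, SE 0.12) and Ppp1r15a (0.63, SE 0.16) rose, and the cystine transporter gene Slc7a11, which held both heptamers in its 3' UTR, fell by 0.91 on the log2 scale (SE 0.11).

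Further lists had at least 25% of their members called in footprints without passing as lists (adjusted p between 0.055 and 0.871). That share is close to the one over all genes, 2667 of 11256. Among genes of the tunnel exit and nascent chain, 8 of 40 fell, such as Srp72, Sec62 (-0.39, SE 0.09), Nmt2 (-0.31, SE 0.09) and Metap2 (-0.31, SE 0.09), and 2 rose; adjusted over the list alone the counts were the same. Among reported Ebp1 partners, Npm1 and Suz12 (-0.37, SE 0.10) fell and Rb1 rose (0.35, SE 0.11), with Akt1 at 0.27 (SE 0.11) not passing. Of the 10 genes, 3 rose and 2 fell adjusted over the list alone. Of 51 genes of G1/S and DNA replication, 7 rose, such as E2f7 (0.65, SE 0.11) and Ccnd1 (0.50, SE 0.10). Another 13 fell, such as E2f8 (-0.64, SE 0.12) and E2f3 (-0.57, SE 0.10), with 8 higher and 15 lower adjusted over the list alone. Of 48 genes of G2/M, 12 fell, such as Mki67 (-0.78, SE 0.13), Tpx2 (-0.46, SE 0.09), Kif23 (-0.40, SE 0.10) and Ube2c (-0.39, SE 0.10), and 2 rose, with the same counts adjusted over the list alone. Genes of the interferon response rose in 7 of 25 cases, such as the RNA sensor genes Ddx58 (0.94, SE 0.16) and Ifih1 (0.97, SE 0.17), Bst2 (0.61, SE 0.11) and Stat2 (0.42, SE 0.09). They fell in 2, with the same counts adjusted over the list alone. Of 25 immediate early genes, 6 rose, such as Dusp4 (0.66, SE 0.11), Nr4a2 (0.71, SE 0.21) and Ier2 (0.40, SE 0.13). Myc fell by 0.56 on the log2 scale (SE 0.10), with 7 higher and 1 lower adjusted over the list alone. The polyamine synthesis list also held genes of hypusine enzymes and antizymes, and only such genes were among the 4 of its 10 members that rose. These were the hypusine enzyme genes Dohh (0.61, SE 0.14) and Dhps (0.27, SE 0.09) and the antizyme genes Oaz1 (1.16, SE 0.27) and Oaz2 (0.62, SE 0.18). Another 1 fell, with 5 higher and 1 lower adjusted over the list alone.

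None of the neuronal and lineage lists below passed as a list in footprints (adjusted p between 0.0622 and 0.871). In the neurite and neuronal cytoskeleton list 9 of 28 members fell, such as Gap43 (-0.68, SE 0.10), the intermediate filament genes Prph (-0.58, SE 0.09) and Nefh (-0.51, SE 0.10), and Stmn2 (-0.42, SE 0.09). Another 1 rose, with 10 lower and 1 higher adjusted over the list alone (list adjusted p = 0.0622). Among axon guidance genes, 5 of 31 rose, such as Sema4c (0.79, SE 0.09) and, at a low level, Efna1 (2.0, SE 0.33; 0.65 to 2.44 CPM). Another 5 fell, such as Plxnd1 (-0.79, SE 0.11) and Nrp1 (-0.42, SE 0.09), with 6 higher and 5 lower adjusted over the list alone. Of 22 noradrenergic and cholinergic neuroblast markers, 5 rose, such as Ddc and Sox11 (0.85, SE 0.15). Another 3 fell, such as Dbh and the nicotinic receptor gene Chrna3 (-0.84, SE 0.10), with 5 higher and 4 lower adjusted over the list alone. Of 15 neural progenitor and Notch genes, 5 rose, such as Notch2 (0.69, SE 0.10), Hey1 (0.61, SE 0.13) and Id4 (1.15, SE 0.30). Another 3 fell, such as Vim (-0.39, SE 0.10), with 5 higher and 4 lower adjusted over the list alone. Of 9 mesenchymal markers, 5 fell, such as Sparc (-0.89, SE 0.12), Lgals1 (-0.65, SE 0.09) and S100a6 (-0.54, SE 0.10). Another 2 rose, Pdgfra among them (1.75, SE 0.30), with 5 lower and 3 higher adjusted over the list alone. Among the list members named for footprints, a 3' UTR copy of CTCACCT or GAACCCT was also held by Gap43, Chrna3, E2f3, Nmt2, Tpx2, Ube2c and Mrpl28, which fell, and by Mrpl20, Dohh and Id4, which rose.

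**Figure D2:**
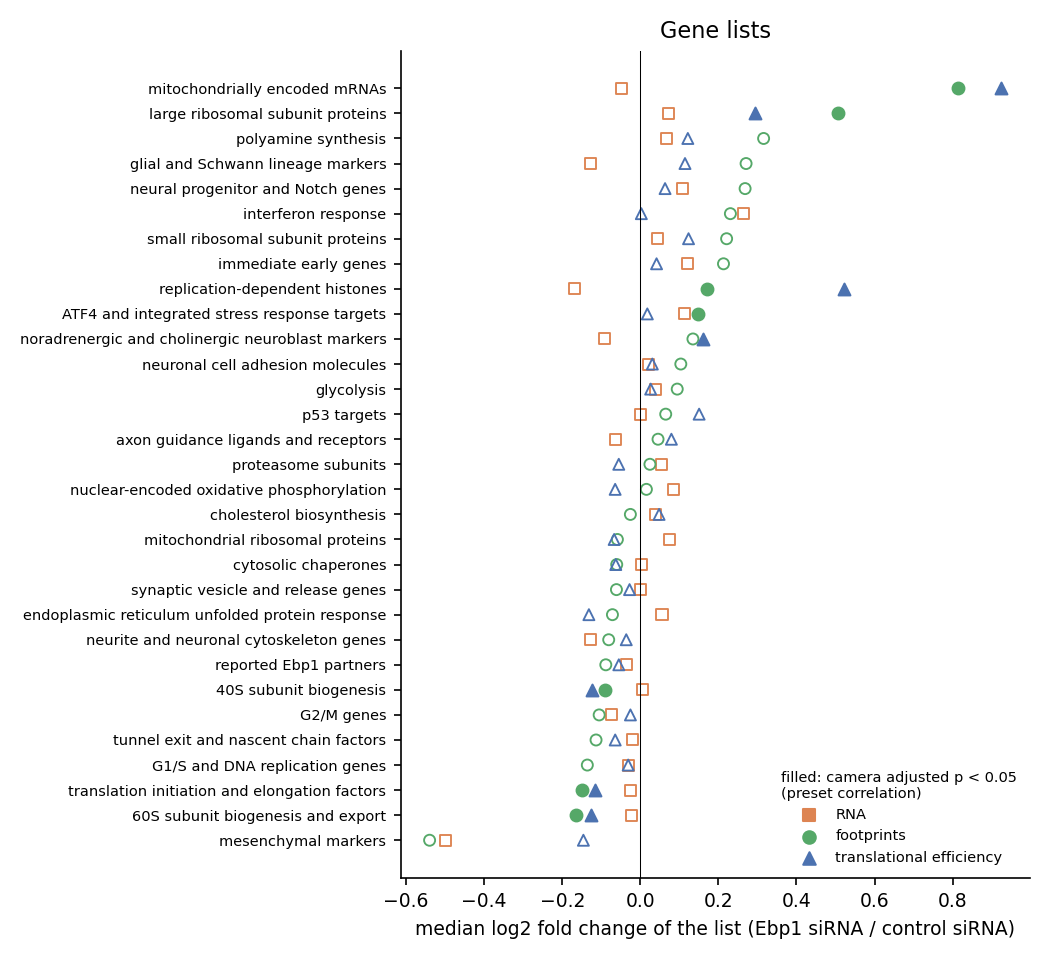
Median log2 fold change (x axis, Ebp1 siRNA over control siRNA) of 31 gene lists (y axis, ordered by the footprint median) in RNA, footprints and translational efficiency; filled symbols passed camera with a preset correlation at an adjusted p under 0.05. No list passed in RNA, and 7 passed in footprints and 7 in translational efficiency. With an estimated correlation or with fry, no list passed in any of these. The footprint median of histones turned to -0.22 with the GC and length trend removed.

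The footprint count was 1542 without control replicate 2, 1602 without control replicate 1 and 1765 without Ebp1 siRNA replicate 3, and 1206 genes also had a log2 fold change of at least 0.5 in size. With each library's trend with coding GC content and length removed, the lists of large ribosomal subunit proteins, 60S biogenesis and 40S biogenesis no longer passed (adjusted p = 0.0814, 0.0964 and 0.295). Their medians were then 0.49 against 0.51, -0.08 against -0.17 and -0.08 against -0.09, and 5 of the 40S genes fell and 3 rose. The neurite and cytoskeleton list (median -0.22, 12 lower and 0 higher, adjusted p = 0.000223) and the interferon list (median 0.19, adjusted p = 0.0437) passed with the trend removed. These became adjusted p = 0.861 and 0.941 with an estimated correlation. The G2/M counts became 7 lower and 7 higher (adjusted p = 0.979), and the immediate early counts 2 and 2 (adjusted p = 0.890). With a filter of 4 CPM the large ribosomal subunit proteins (median 0.16, adjusted p = 0.730), 60S biogenesis (median -0.15, 0.0603) and 40S biogenesis (median -0.07, 0.0603) did not pass, nor did the ribosomal proteins after thinning (median 0.30, 0.279). With 1 library left out, the ribosomal proteins did not pass without control replicate 1 (median 0.34, 0.141) or Ebp1 siRNA replicate 2 (median 0.33, 0.177), and 60S biogenesis not without control replicate 2 (0.121) or Ebp1 siRNA replicate 1 (0.0822). The 40S list did not pass without control replicate 2 (0.128) or Ebp1 siRNA replicate 3 (0.0855).

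The changes in RNA and in footprints were compared across genes. Most genes that changed in RNA changed in the same direction in footprints. Of the 12 higher RNA genes measured in both assays all 12 were called higher in footprints. Of the 71 lower genes 63 were called lower, where independent lists would share 1.36 and 8.97. The libraries of both assays came from the same cultures, so independence is not the value to be met without an effect. No gene was called in opposite directions. The 8 genes called lower in RNA and not called in footprints were Neurl3, Gas2l1, Nacad, Rnf187, Card19, Gm20517, Sh3glb2 and Rnf166, all but Rnf166 chosen after their values were seen. Rnf166 changed by -0.49 in footprints (SE 0.20, adjusted p = 0.0762). Of the genes called in footprints, 1132 of 1237 higher genes (91.5%) and 1283 of 1377 lower genes (93.2%) had RNA changes of the same sign. Their median RNA log2 fold change was 0.24 against 0.52 in footprints for the higher and -0.26 against -0.44 for the lower genes. These genes were selected by their footprint values, which favours larger values there.

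Over the 10894 genes tested in both assays, the log2 fold changes correlated with a Pearson r of 0.658 and a Spearman rho of 0.628 across genes, which are not independent replicates, and 73.0% had the same sign. The total-least-squares slope was 0.706 in RNA per unit in footprints, and 0.699 without Pa2g4. The RNA and footprint libraries came from the same cultures, so part of the correlation can be shared culture differences.

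**Figure D3:**
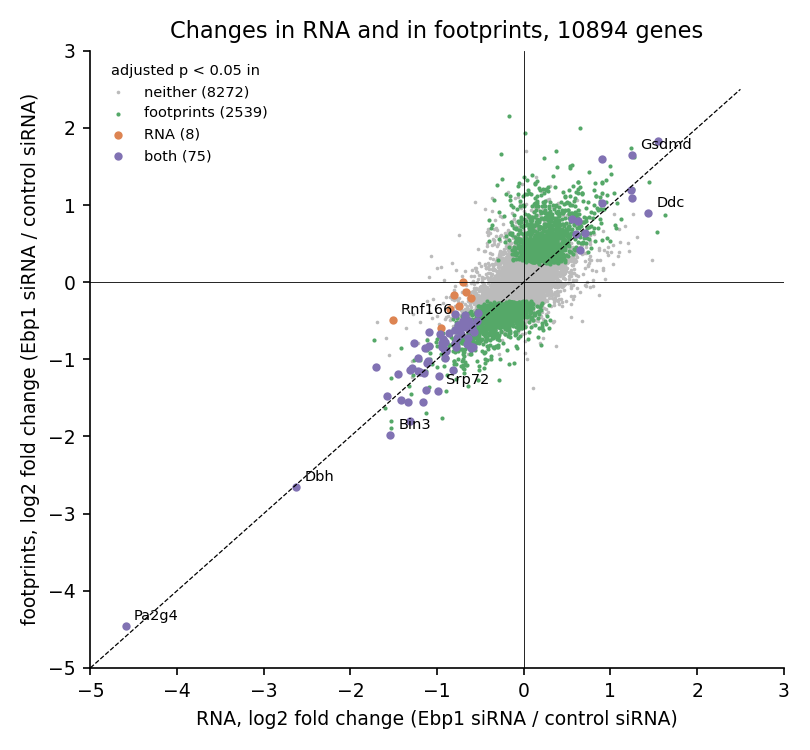
Log2 fold change (Ebp1 siRNA over control siRNA) in RNA (x axis) and in footprints (y axis) of 10894 genes, coloured by the assay in which the gene was called, with the line of equal change dashed. The 63 genes called lower in both assays lie near that line, with Pa2g4 at -4.59 and -4.46 and Dbh at -2.63 and -2.65.

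Translational efficiency was tested to ask which genes changed in footprints beyond their mRNA. No single gene passed. edgeR called 0 of 10894 genes, with 708 at an unadjusted p under 0.05 where 545 were to be met by chance, and the smallest adjusted p was 0.276. A split of control cultures 1 and 2 and Ebp1 siRNA culture 3 against the other cultures gave 1082 genes with such a p. The remaining splits that mixed the treatments gave between 52 and 284. The excess of the 708 thus need not come from the treatment. DESeq2 called 5 genes, all higher, and limma on the per-culture ratios called 0. The DESeq2 genes were Bok, a BCL2 family member (log2 fold change 1.08, SE 0.23), Hnrnpa0 (1.04, SE 0.22), the oligosaccharyltransferase subunit gene Ost4 (1.13, SE 0.26), Rpl38 (2.33, SE 0.53) and D930007J09Rik (1.93, SE 0.39). D930007J09Rik was chosen after its values were seen. Without control replicate 3, edgeR called 5 genes, Hnrnpa0, Ost4, Rpl41, Rplp1 and Selenoh, all higher, Selenoh being chosen after its values were seen. For 86.2% of the genes the 95% interval of the change lay within 1 log2 unit either way. It lay within 1.5-fold either way for only 47.0% of the genes. In the simulation, 23.9% of the genes changed by 1.5-fold were recovered in this comparison. The absence of calls thus does not exclude changes of about that size in many genes. Nor can it exclude a change in translation common to all genes, since the scaling removes it.

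The genes with the smallest p among those with a mean of at least 4 CPM and a higher ratio in all 3 Ebp1 siRNA cultures, none of which passed, were Bok (log2 fold change 1.07, SE 0.21, adjusted p = 0.352), Hnrnpa0 (1.04, SE 0.21), Ost4 (1.13, SE 0.23), Rpl41 (1.03, SE 0.23) and Hmgn2 (1.21, SE 0.28). The RNA change of Hnrnpa0 was 0.08 (SE 0.09) while its footprints rose by 1.14 (SE 0.19, adjusted p = 0.00347). Under the same limit, those with a lower ratio, also not passing, were Sgo1, a protector of centromere cohesion (-0.59, SE 0.16, adjusted p = 0.684), Gzf1 (-0.59, SE 0.16), the splicing kinase gene Srpk1 (-0.46, SE 0.13), Selenok (-0.89, SE 0.26) and Wee1, a kinase that holds back entry into mitosis (-0.54, SE 0.16).

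As lists, 7 passed camera on the per-culture ratios, and none with an estimated correlation or with fry. Mitochondrially encoded mRNAs were higher (median log2 fold change 0.92, 7 of 7 positive, adjusted p = 5.4e-06; adjusted p = 0.833 with an estimated correlation). None was called among all genes and 7 were higher adjusted over the list alone. The estimated inter-gene correlation of this list was 0.98, so its 7 members moved nearly as 1 and are not separate evidence. mt-Nd5 stood at 1.07 (SE 0.31), mt-Co1 at 1.07 (SE 0.35), mt-Nd4 at 0.92 (SE 0.28) and mt-Nd1 at 0.84 (SE 0.27). Their footprint share differed between cultures of one treatment, as given above. Large ribosomal subunit proteins were higher (median 0.29, 27 of 39 positive, adjusted p = 0.0249; adjusted p = 0.890 with an estimated correlation). Adjusted over the list alone 3 were higher, with members at 2.31 (Rpl38, SE 0.42), 1.29 (Rplp1, SE 0.37), 1.03 (Rpl41) and -0.69 (Rpl23, SE 0.25). The 6 measured histones had a median of 0.52 (5 of 6 positive, adjusted p = 0.0385; adjusted p = 0.833 with an estimated correlation). Histone genes took at most 0.00361% of the poly(A)-enriched RNA counts, so their ratios are not usable as translational efficiency. RNA was near the floor for Hist1h2bc, 2.04 to 1.16 CPM, and Hist2h2bb, 1.58 to 0.883 CPM, with footprint values of -0.10 and -0.19. Hist1h1c stood higher, at 6.43 and 6.46 CPM in RNA, with a footprint change of 0.55 (SE 0.13). No histone was called adjusted over the list alone. Ratios stood at 0.69 (SE 0.39) for Hist1h2bc, 0.66 (SE 0.37) for Hist2h2bb, 0.53 (SE 0.26) for Hist1h1c and 0.52 (SE 0.39) for Hist3h2a. Neuroblast markers were higher (median 0.16, 17 of 22 positive, adjusted p = 0.0249; adjusted p = 0.890 with an estimated correlation). Adjusted over the list alone 1 was higher, with values from Sox11 (0.78, SE 0.21), Phox2a (0.62, SE 0.23) and Sox4 (0.48, SE 0.20) to Ddc (-0.55, SE 0.19).

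The biogenesis and factor lists were lower in translational efficiency. Genes of 60S biogenesis had a median of -0.13, with 30 of 39 negative (adjusted p = 0.00217; adjusted p = 0.833 with an estimated correlation). Among them were Ncl (-0.58, SE 0.21), Zfp622 (-0.56, SE 0.20), Nvl (-0.42, SE 0.16) and Rpf1 (-0.40, SE 0.16). Genes of 40S biogenesis had a median of -0.12, with 27 of 34 negative (adjusted p = 0.00217; adjusted p = 0.833 with an estimated correlation). Among them were Utp3 (-0.47, SE 0.18), Nop14 (-0.34, SE 0.15), Ltv1 (-0.32, SE 0.17) and Pno1 (-0.28, SE 0.15). Translation factors had a median of -0.12, with 35 of 45 negative (adjusted p = 0.016; adjusted p = 0.890 with an estimated correlation). Members stood at -0.39 for Eif3c (SE 0.13), -0.37 for Eif4b (SE 0.15), -0.37 for Eif4e (SE 0.14) and 0.62 for Eef1g (SE 0.22). No member of these 3 lists passed, adjusted over all genes or over the list alone. Of the genes named only for translational efficiency, Ost4, Gzf1, Sox4 and Zfp622 held a 3' UTR copy of a heptamer. Without Ebp1 siRNA replicate 3, the 60S list (median -0.05, adjusted p = 0.206), the 40S list (median -0.08, 0.179), the histones (median 0.44, 0.141), the neuroblast markers (median 0.09, 0.277) and the factor list, whose median turned to 0.02, did not pass. Without control replicate 1 the ribosomal proteins (median 0.08, 0.776), histones (median 0.28, 0.198) and neuroblast markers (median 0.11, 0.099) did not. The ribosomal protein list was also lost without Ebp1 siRNA replicate 2 (median 0.10, 0.951) or with a filter of 4 CPM (median 0.10, 0.857), and the factor list without control replicate 3 (0.0697). Not passing with the GC and length trend removed were the histones (0.381) and the neuroblast markers, whose median turned to -0.02 (0.751). Mitochondrial ribosomal proteins passed with the trend removed (median -0.09, adjusted p = 0.0172; adjusted p = 0.860 with an estimated correlation).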

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

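The settings chosen after seeing the data were the removal of the GC and length trend, thinning, removal of genes with a heptamer site, the culture block with the trend removed and, for the correlation across genes, DESeq2 fold changes, trend removal and each library left out. The Pa2g4 knockdown kept its call throughout, between -4.77 and -4.44 in RNA and between -4.71 and -4.29 in footprints with 1 library left out. The 84 RNA calls became 292 with DESeq2, 146 without a low-count filter, 419 in 1 fit over all 12 libraries, 364 with the GC and length trend removed and 36 without genes that hold a heptamer site, where fewer genes were tested. With 1 library left out they ranged from 4 to 793. The 2667 footprint calls ranged from 1542 to 3010 with 1 library left out, were 2073 after thinning, and 1206 also had a log2 fold change of at least 0.5. The 0 translational efficiency calls became 5 with DESeq2 and ranged from 0 to 5 with 1 replicate left out. The correlation of 0.658 across genes was 0.628 with ranks, 0.697 at 4 CPM or more, 0.688 with the trend removed and between 0.593 and 0.684 with 1 library left out.

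Among the lists described for an assay, the medians that turned were those of histones in footprints with the trend removed (-0.22), axon guidance genes in footprints at 4 CPM (-0.14) and after thinning (-0.0451), neuroblast markers with the trend removed in footprints (-0.0630) and translational efficiency (-0.0239), and mesenchymal markers in footprints without a filter (0.23). The translation factor median in translational efficiency ranged from -0.18 without siEbp1 replicate 2 to 0.0183 without siEbp1 replicate 3. Why these medians turned was not tested in any setting.

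Replicate numbers did not pair the treatments in RNA, where libraries of the same number deviated with an r of -0.29, -0.02 and -0.56. In footprints the r values were all positive, at 0.09, 0.14 and 0.36. The main tests did not pair by number, and whether the numbers mark a shared batch was not tested. With the replicate number as a block the calls were 1 in RNA, 3496 in footprints, against 2667 without it, and 0 in translational efficiency. The large ribosomal subunit list then did not pass camera in footprints (median 0.49, adjusted p = 0.0738). A culture block gave 0 calls in translational efficiency, also with the trend removed.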

Other observations

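Of the tests below, the removal of the GC and length trend, thinning and the follow-up of the 2 heptamers were chosen only after the results were seen. Further groups had fewer of their members called in footprints, and none passed as a list before the trend was removed. Among nuclear-encoded oxidative phosphorylation genes 11 of 75 rose and 7 fell (camera adjusted p = 0.533), among proteasome subunits 6 of 37 rose and 3 fell (0.6002), and among synaptic vesicle genes 2 of 40 rose and 7 fell (0.190). With the trend removed the synaptic vesicle list passed (0.0437; adjusted p = 0.941 with an estimated correlation; 2 rose, 10 fell). Of 18 p53 targets 4 rose and none fell (0.367), and of 21 glycolysis genes none rose and 2 fell (0.871).

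More genes were called in footprints than in RNA, 2667 against 84. The gap depended on 1 RNA library and on the fit: 793 RNA genes were called without Ebp1 siRNA replicate 3, and 1 fit over all 12 libraries called 1790 and 419. Greater depth of the footprint libraries did not account for this, since 2073 were called after thinning to the smallest RNA total. Trends with coding length and GC content between libraries did not account for all of it, since 364 RNA genes were called with the trend removed. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave at least 84 RNA calls: the real one with 84 and 1 other with 535. That other split, of control replicates 1 and 2 and Ebp1 siRNA replicate 3 against the rest, points to a structure of the RNA libraries, and gave 52 calls with the trend removed. Deviations from the mean of the 6 RNA libraries followed coding length in part. The rank correlations were -0.33, 0.01 and -0.46 in those 3 libraries. They were 0.39 in control replicate 3, and 0.22 and 0.32 in Ebp1 siRNA replicates 1 and 2. In footprints only 1 of 10 splits, the real one, reached 2667, with 0 the highest other. In translational efficiency the real count was 0, which every split reaches whatever the data, so the splits cannot decide there. These splits are too few for a share under 0.05.

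Footprint changes were higher in genes with a higher coding GC content (rank correlation 0.41), as were those in translational efficiency (0.41), against 0.14 in RNA. Differences in GC bias between libraries, unrelated to treatment, could give this in footprints. There, 5 of the 9 other splits had a correlation as large in size, up to 0.61. The trend did not account for the footprint calls as a set, since 2931 genes were called with it removed, 2032 of them among the 2667. No biological explanation was tested.

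Genes that fell after Ebp1 siRNA could in part be off-target genes of the siRNAs, whose sequences were not used here. Of the 20 heptamers whose 3' UTR sites went with the lowest footprint changes, 7 occur in the Pa2g4 mRNA where 2.78 were to be met by chance (exact hypergeometric p = 0.0146, with overlapping heptamers not independent). The strongest, CTCACCT and GAACCCT, had t values of -13.3 and -11.0 in RNA, against -4.34 for the lowest heptamer without TCACC, CACCT, AACCC or ACCCT in it. Sites of either were in 50.7% of 69 RNA falls, 30.9% of 1354 footprint falls and 19.1% of searched genes. Of 2096 genes with a site of either in the coding sequence only, 16 were called lower in RNA (median log2 fold change -0.02). Of 6767 genes with neither in 3' UTR nor coding sequence, 18 were called lower (median 0.04). In footprints 280 of 2094 and 655 of 6737 such genes were called lower. These classes were not matched for coding length. Both heptamers were picked from these same changes, so none of this is a separate test. Sites of any of the 11 heptamers that passed a Bonferroni threshold were in 73.9% of the RNA falls and in 48.3% of all searched genes; for the 1354 footprint falls and 12 heptamers the shares were 59.2% and 51.1%. Sites of the 11 heptamers were in 51 of the 69 RNA falls, so sites in the searched 3' UTRs do not directly account for the others. Sites of the 11 in coding sequences were not counted for these falls. With sites of the whole set this common, how large a part seed matches gave cannot be told, nor whether matches outside this set gave the rest. No test separated seed-match falls from effects of losing Ebp1.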
